A study of Homo sapiens with 6 samples.

How the data were processed

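Single-nucleus RNA-seq libraries of human left ventricle were compared, 3 from healthy hearts and 3 from hearts with non-ischaemic cardiomyopathy (NICM). The healthy libraries are those titled as source, which the series text sets against NICM as hearts without known cardiovascular disease. Per the labels, each library carries its own title and nothing ties any pair of them to 1 person, so the 6 libraries were taken as 6 people as far as stated. Replicate numbers follow the order of the samples and pair nothing. The series text names frozen tissue from ventricular assist device cores or from the matching part of the apex, isolation of nuclei, and a sort of nuclei positive for the DNA dye DRAQ5. It names a 3′ and a 5′ droplet kit from 10x Genomics without saying which library was made with which.

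The deposited values are whole-number UMI counts per gene and barcode in sparse matrices, written by Cell Ranger 6.0.0 per the file headers, with the build GRCh38 per the submitters' processing notes. The matrices hold 33538 genes and 75807 barcodes in all. They hold called barcodes rather than all droplets, so free RNA could not be measured in empty droplets. The counting of intronic reads and the annotation used by the authors are not given in the sources used here. Gene coordinates were taken from GENCODE 29 on GRCh38, to which 33456 of the gene identifiers matched. The 102 genes on the Y chromosome and the X-inactivation transcripts were left out before any step.

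Barcodes were compared between libraries before any comparison of the groups. Chance was set from these same 15 pairs, by the median size of a common barcode list that their sharing implied. Ratios are therefore centred on 1 by construction, and only their spread and outliers are informative. In 14 of the 15 pairs of matrices, sharing was between 0.893 and 1.07 times that of chance. In the remaining pair, 1 NICM matrix held 92.5% of the barcodes of 1 healthy matrix. These shared barcodes, 48.5% of that NICM matrix, were removed from it because sharing was over 3 times chance. That rule was set after the barcodes were seen, and values with these barcodes kept are among the alternatives.

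Nuclei with at least 500 UMIs, at least 300 genes and under 5% mitochondrial UMIs were kept. In each library the nuclei with the highest Scrublet scores (scanpy 1.11.5) were removed as doublets, 0.4% per 1000 barcodes, which removed between 3.73% and 5.00% of the scored nuclei. This left 57941 nuclei, 32619 from healthy and 25322 from NICM libraries. Clustering used 3000 variable genes ranked within libraries, 30 principal components, 15 neighbours and Leiden resolution 1.0 (igraph 0.11.9), with no integration across libraries. A cluster took a cell type's name when that type had the highest mean z score of its markers, at least 1, when no unrelated type also reached 1, when at least 3 markers were seen in 10% of its nuclei at a log2 difference of 1 or more, and when under 50% of its nuclei were called doublets. A cluster also stayed unnamed when its top 10 genes (each in at least 25% of its nuclei) held more genes of another type than of its own. For that count, the markers and the gene lists specific to a type were pooled, a rule set after the clusters were seen. Of 46 clusters, 33 were named, holding 54104 nuclei of 14 types, and 3837 nuclei stayed unnamed. At Leiden resolution 2.0, 48 of 67 clusters were named. These names rest on marker genes and were not checked against an annotation by the authors, which was not used here.

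Counts were summed per library for the 7 cell types whose comparison was fixed in advance, on the condition of at least 20 nuclei in every library, which all 7 met. Endocardial, lymphatic endothelial, neuronal and mast cells also had at least 20 nuclei in every library (lowest 71, 39, 47 and 20), but were not among the types fixed and were not tested across genes. Genes were tested with edgeR 4.0.16 (R 4.3.3), using filterByExpr, TMM scaling and the quasi-likelihood test with the group as the only term, and p-values were adjusted by Benjamini-Hochberg within a type at a threshold of 0.05. The 6 summed libraries of a type held between 255595 and 992208 UMIs in smooth muscle cells and between 8549177 and 56429341 in cardiomyocytes. CPM values given with gene tests were scaled by TMM, and fold changes are NICM over healthy. Gene lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry, which tests a list by itself. A list needed 5 measured members. The 26 gene lists, the 14 marker lists, the tests, the filters, the clustering settings, the rule for naming genes and most alternatives were fixed before the data were examined. Adjusted p-values "over the list alone" were adjusted by Benjamini-Hochberg within 1 list. Cell type shares, depth and quality were compared with exact two-sided permutation tests, for which 3 libraries against 3 give 10 splits and no p below 0.1. Whether a change differed between a pair of cell types was tested with limma on the differences within libraries, a test chosen after the changes within each type were seen. Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, doublets kept, at least 1000 UMIs per nucleus, Leiden resolution 2.0, genes open to free RNA left out, shared barcodes kept, and each library left out in turn.

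Genes were named by rule. In fibroblasts, cardiomyocytes, endothelial cells, pericytes and myeloid cells these were the 10 largest rises and the 10 largest falls, and in smooth muscle cells and lymphocytes the 4 largest each way. They were taken among genes that passed the test, did not overlap between the groups, reached a mean of 10 CPM in the higher group and stood in that type at 0.5 or more of their level in all nuclei. Members of the fixed lists could be named whether or not they passed. Sex-linked genes that differ between people by sex, HLA genes, receptor and immunoglobulin segments and genes with common deletions were not named. The symbol CTGF in the files is the older symbol of CCN2. ADRBK1 and TRHDE-AS1 of the fixed lists were not measured. Reads of HSPA1A and HSPA1B, and of the metallothionein genes (MT2A and the MT1 genes), come from near-identical sequences, so how they split between these genes is uncertain.

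The procedure was tested on simulated counts with the real means, library sizes and spread, with 100 genes changed 2-fold and 100 changed 4-fold. For 4-fold changes it recovered 2% in cardiomyocytes, 24% in fibroblasts, 59% in endothelial cells, 79% in pericytes, 82% in smooth muscle cells, 66% in myeloid cells and 73% in lymphocytes. For 2-fold changes it recovered 0%, 0%, 5%, 9%, 14%, 9% and 13% in the same order. Among all simulated calls, 1 of 3, 3 of 27, 9 of 73, 13 of 101, 5 of 101, 10 of 85 and 3 of 89 were false in the same order, over 5% in all types but smooth muscle cells and lymphocytes. In each of the 7 types camera called a simulated list of 20 genes changed by 1 on the log2 scale, and called 0 of 20 unchanged lists. The simulated genes varied independently of each other. These counts therefore do not show how often lists of genes that vary together are called falsely. The spread between people, as edgeR's biological coefficient of variation, was 46.4% in cardiomyocytes, 37.2% in fibroblasts, 33.6% in endothelial cells, 31.5% in pericytes, 28.3% in smooth muscle cells, 32.7% in myeloid cells and 26.8% in lymphocytes.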

Results

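Nuclei were profiled from the left ventricle of 3 healthy hearts and 3 hearts with NICM, heart failure that does not arise from blocked coronary arteries or infarction. The design asks how the cells of the failing ventricle differ from those of healthy ventricle, cell type by cell type. After filtering, healthy replicates 1 to 3 held 9939, 11403 and 11277 nuclei with 52554318, 78836767 and 110747683 UMIs. NICM replicates 1 to 3 held 9360, 8596 and 7366 nuclei with 61026048, 51839539 and 54737155 UMIs. The median UMI count per nucleus was 4970 ± 1149 in healthy and 4863 ± 693 in NICM libraries (SD, n = 3 libraries each, exact permutation p = 0.9). The median number of genes was 2336 ± 404 against 2249 ± 244 (exact permutation p = 0.9). With every nucleus thinned to 1000 UMIs, the median number of genes was 733 ± 3.51 against 720 ± 8.33 (exact permutation p = 0.2), leaving out 848 and 610 shallower nuclei. This difference, NICM minus healthy, was larger within endothelial cells (−28.0 genes), myeloid cells (−24.8) and lymphocytes (−37.5). In these types it stayed negative with each library left out in turn. Values of the other types are not given here. NICM libraries lost a larger part of their barcodes to the mitochondrial limit, 14.0% ± 3.58 against 3.20% ± 1.83. Over all barcodes before this filter, without the shared ones, the median mitochondrial share was 2.12% ± 0.658 in NICM against 1.04% ± 0.357 in healthy libraries. The groups did not overlap in either measure (exact permutation p = 0.1 for both, the smallest the design allows).

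The main types of cardiac cell were found in both groups. Cardiomyocytes, the contracting cells, made up 16.6% ± 8.59 of healthy and 12.6% ± 3.54 of NICM nuclei (SD, n = 3, exact permutation p = 0.5). Fibroblasts, which make the extracellular matrix, made up 17.7% ± 1.71 and 24.4% ± 5.60 (exact permutation p = 0.2), and endothelial cells of blood vessels 21.6% ± 3.00 and 21.1% ± 8.31 (exact permutation p = 1). Pericytes, the mural cells of capillaries, made up 14.0% ± 6.63 and 6.06% ± 4.02 (exact permutation p = 0.2). Lymphatic endothelial cells were the only named type whose libraries did not overlap at these settings, with 0.495% ± 0.162 of healthy and 1.77% ± 0.753 of NICM nuclei, 3.57 times as high (exact permutation p = 0.1, edgeR on nucleus counts adjusted p = 0.171). Myeloid cells made up 12.1% ± 4.17 and 15.4% ± 0.872 (exact permutation p = 0.3) and lymphocytes 2.95% ± 1.32 and 3.82% ± 0.676 (exact permutation p = 0.4). Smooth muscle cells made up 1.33% ± 0.581 and 1.26% ± 0.413 (exact permutation p = 0.9), and endocardial cells, which line the chambers, 4.33% ± 4.87 and 2.52% ± 1.78 (exact permutation p = 0.7). The smooth muscle share leaves out unnamed cluster 21, whose markers scored highest for smooth muscle cells. That cluster made up 0.503% of healthy and 4.87% of NICM nuclei, so the like shares of smooth muscle cells depend on the naming rule. Mast cells made up 1.42% ± 0.698 and 0.611% ± 0.358 (exact permutation p = 0.2) and adipocytes 0.341% and 1.27% (exact permutation p = 0.7). Neuronal cells (1.28% and 0.940%, exact permutation p = 0.5), B cells (0.203% and 0.119%, exact permutation p = 0.6) and mesothelial cells (0.242% and 0.0129%, exact permutation p = 0.4) were rarer. Nuclei without a named type made up 5.44% ± 0.815 and 8.13% ± 1.90 (exact permutation p = 0.1). No share passed a test, the smallest p the design allows being 0.1, and these are shares of nuclei that had been sorted on DRAQ5 and had passed a mitochondrial limit that removed more NICM barcodes.

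**Figure D1:**
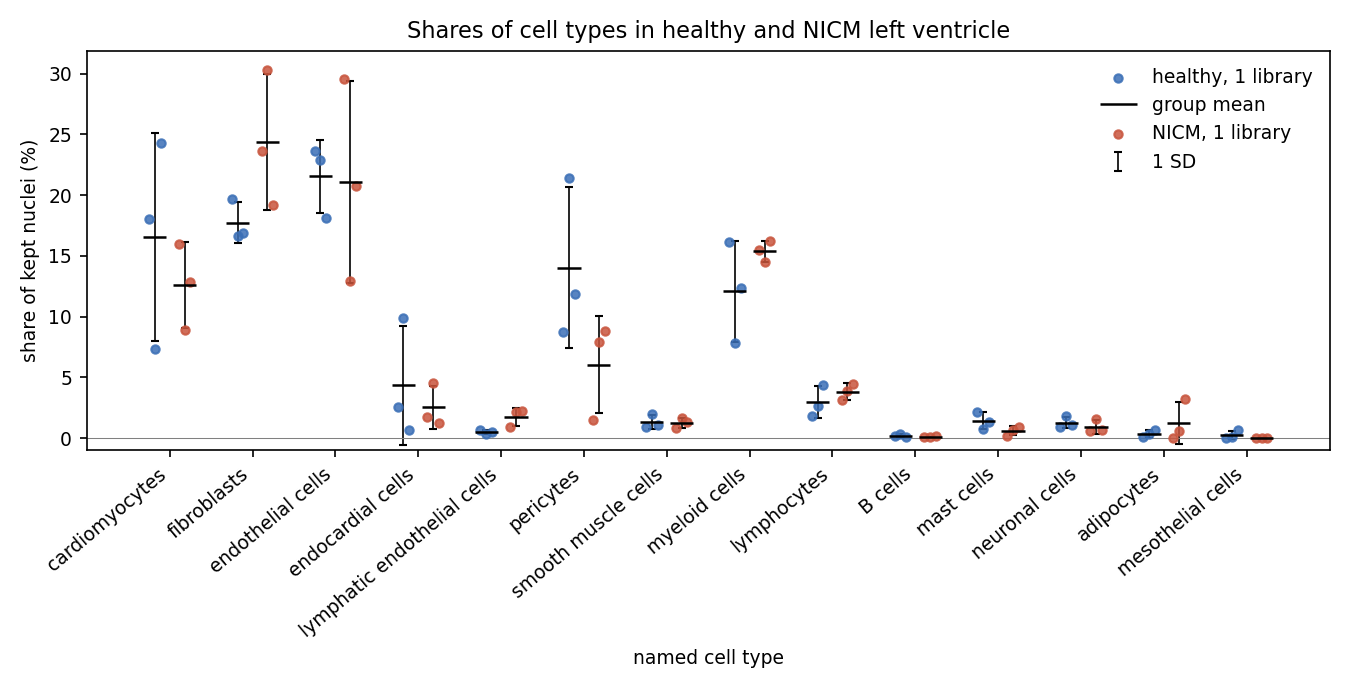
Share of kept nuclei (%, vertical axis) of each named cell type (horizontal axis) in healthy (blue) and NICM (red) libraries, with 1 point per library, the group mean as a bar and 1 SD as whiskers. Lymphatic endothelial cells, at 0.495% and 1.77%, are the type whose groups do not overlap.

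Fibroblasts of NICM hearts differed from healthy ones in 49 of 16698 genes tested, 28 higher and 21 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05). The natriuretic peptide genes NPPA and NPPB rose. NPPA went from 5.06 ± 1.70 to 226 ± 144 CPM (log2 change 5.48 ± 0.59 SE, adjusted p = 0.0213), a level much alike in every tested type of NICM libraries. NPPB went from 2.26 to 59.1 CPM (4.64 ± 0.67, adjusted p = 0.0443). In the other tested types NPPB was also higher in every NICM library than in every healthy one. Its NICM level before TMM scaling was 58.9 CPM in fibroblasts, the lowest of the 7 tested types, and from 76.1 in myeloid cells to 180 in cardiomyocytes. CORIN, the protease that activates the NPPA product, rose from 10.7 ± 2.26 to 75.8 ± 13.5 CPM (2.83 ± 0.28, adjusted p = 0.0172). Among the other named rises, HAPLN1, which links hyaluronan to proteoglycans, went from 12.7 ± 2.25 to 115 ± 33.1 CPM (3.18 ± 0.31, adjusted p = 0.0172). LAMB1, a laminin chain, is not among the 10 largest rises and is given as a member of the extracellular matrix list. It went from 509 ± 130 to 2084 ± 235 CPM (2.03 ± 0.30, adjusted p = 0.0443). The named rise ITGA10, a subunit of a collagen-binding integrin, went from 1.65 to 18.4 CPM (3.45 ± 0.46, adjusted p = 0.0393). Among the named falls were genes of secreted factors. The growth factor gene FGF10 went from 91.3 ± 26.8 to 3.22 ± 0.590 CPM (−4.81 ± 0.34, adjusted p = 0.0037) and FGF7 from 1176 ± 726 to 57.9 ± 18.5 CPM (−4.34 ± 0.51, adjusted p = 0.0302). The C-type natriuretic peptide gene NPPC (−4.85 ± 0.64, adjusted p = 0.0372) and the chemokine gene CXCL1 (−5.52 ± 0.86, adjusted p = 0.0477) fell as well.

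The other named rises in fibroblasts were AFF2 (log2 change 3.65), SEZ6L (3.56), ARHGEF26 (2.95), KIAA1211 (2.69) and MAP2, a microtubule-binding protein gene (2.66). The other named falls were ADAMTS4, a protease of aggrecan (−4.21), PTGES, which makes prostaglandin E (−3.57), TMEM51 (−3.46), HES1, a repressor induced by Notch (−3.40), the endothelin receptor gene EDNRB (−2.86) and STUM (−2.60). All 20 genes named by rule were higher or lower in every NICM library than in every healthy one, which the rule itself required. NPPA (ENSG00000175206) lies on chromosome 1 at 11845709 to 11848345 and NPPB (ENSG00000120937) beside it at 11857464 to 11858931. CORIN (ENSG00000145244) lies on chromosome 4 at 47593998 to 47838106, HAPLN1 (ENSG00000145681) on chromosome 5 at 83637805 to 83721613, FGF10 (ENSG00000070193) on chromosome 5 at 44303544 to 44389706 and FGF7 (ENSG00000140285) on chromosome 15 at 49423096 to 49488775.

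**Figure D2:**
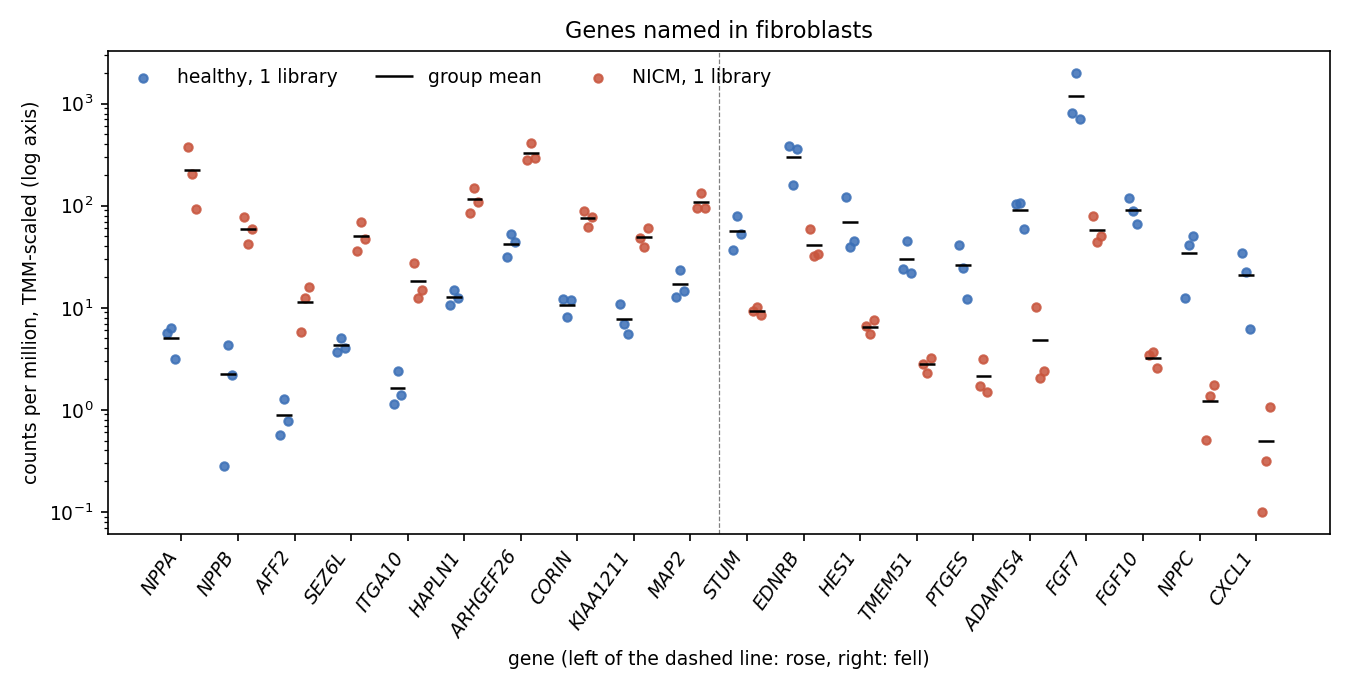
TMM-scaled CPM in fibroblasts (vertical log axis) of the 10 genes named as rising and the 10 named as falling (horizontal axis), with 1 point per healthy (blue) or NICM (red) library and the group mean as a bar. The groups do not overlap for any of the 20 genes, which the naming rule required, and FGF10 goes from 91.3 to 3.22 CPM.

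Among the lists, fibroblasts had a higher activated fibroblast list. Of its 24 measured genes 19 had positive changes (median log2 change 0.89, camera adjusted p = 3.76e-06, adjusted p = 0.209 with an estimated correlation). ITGA10 rose over all genes tested, and ITGA10, CTGF, POSTN, THBS4 and LTBP2 rose adjusted over the list alone (5 rose, 0 fell). POSTN, the matrix protein periostin, had 37.9 CPM in healthy and 358 CPM in NICM libraries (adjusted p = 0.098 over all genes). The extracellular matrix list was higher (28 measured, median 0.31, adjusted p = 0.0453, adjusted p = 0.577 with an estimated correlation). LAMB1 rose over all genes and 3 rose adjusted over the list alone. Glucocorticoid-induced genes were higher (19 measured, median 0.35, adjusted p = 0.00317, adjusted p = 0.209 with an estimated correlation). Adjusted over the list alone 4 rose and 1 fell, FKBP5 among the rises (log2 change 2.68, adjusted p = 0.161 over all genes). The NF-kB and cytokine list was lower (19 measured, adjusted p = 5.59e-07, adjusted p = 0.209 with an estimated correlation). CXCL1 fell over all genes, and 12 of its members, including CCL2, ICAM1 and TNFAIP2, fell adjusted over the list alone. Immediate early genes, which respond within minutes to many stimuli, were lower (22 measured, median −2.21, adjusted p = 1.75e-06, adjusted p = 0.506 with an estimated correlation). The median was −0.73 without healthy replicate 1. Of these genes, 12 fell adjusted over the list alone, among them NR4A3, JUNB and IER3, and the log2 change of NR4A3 went from −6.44 to −2.80 without that library. The hypoxia list was lower (17 measured, median −0.29, adjusted p = 0.0285, adjusted p = 0.209 with an estimated correlation). The angiogenic factor gene VEGFA fell over all genes (162 to 39.1 CPM), and 4 fell adjusted over the list alone. Glycolysis genes (19 measured, median −0.57, adjusted p = 0.00317, adjusted p = 0.424 with an estimated correlation) and heat shock proteins (16 measured, median −0.51, adjusted p = 0.00181, adjusted p = 0.577 with an estimated correlation) were lower with 0 members past either adjustment. Several of these calls were lost with 1 library left out: heat shock proteins without healthy replicate 1 (adjusted p = 0.113), glycolysis without NICM replicate 1 (0.0662), and hypoxia without healthy replicates 2 and 3 and NICM replicate 2 (up to 0.0859). The extracellular matrix list was lost without healthy replicates 2 and 3 and NICM replicates 2 and 3 (up to 0.283). Of 22 measured resting fibroblast genes, the complement gene C3 fell over all genes (672 ± 119 to 133 ± 27.0 CPM), and 3 rose and 4 fell adjusted over the list alone (median −0.10, adjusted p = 0.743). The lists of fatty acid oxidation (median 0.09, adjusted p = 0.499), oxidative phosphorylation (−0.01, adjusted p = 0.973) and interferon response (0.15, adjusted p = 0.129) did not pass. Neither did TGF-beta response (−0.31, against a test direction of up, adjusted p = 0.743), with 2 of 18 rising adjusted over the list alone.

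Markers of other cell types moved in the fibroblast sums too. Cardiomyocyte markers were higher (median 0.21, adjusted p = 0.0265, adjusted p = 0.703 with an estimated correlation) and myeloid markers lower (adjusted p = 0.00431, adjusted p = 0.703 with an estimated correlation). CORIN, a cardiomyocyte marker, and NRG1, an endocardial marker (log2 change 2.62), rose, and PDGFRB, a pericyte marker (350 to 70.5 CPM), fell. In cardiomyocytes themselves CORIN was lower in NICM (316 and 138 CPM without TMM scaling). Its NICM level, also unscaled, was 75.6 CPM in fibroblasts and from 4.02 to 12.1 CPM in the tested types other than cardiomyocytes and fibroblasts. Different clusters held the fibroblasts of the groups: clusters 10, 40 and 11 held 98.6%, 98.9% and 93.05% of those of healthy replicates 1, 2 and 3. The leading genes of cluster 10 include TNFAIP6, EGR3, CYR61 and CCL2. Clusters 35 and 22 held 67.8% and 31.1% of NICM fibroblasts, cluster 22 mostly those of NICM replicate 1. The count of 49 moved to 1, 15, 0 and 2 genes without healthy replicate 1, healthy replicate 2, NICM replicate 2 and NICM replicate 3, and to 20 at Leiden resolution 2.0 and 6 with the shared barcodes kept. All 49 kept their sign in each of these settings. DESeq2 called 675 genes and edgeR without a filter on low counts 452. In 16.1% of genes the groups did not overlap, where chance gives 10%. Here and in the types below, that 10% is the average over all splits of the libraries. Genes vary together within a library, so a single split can lie away from it by chance. The share in the other splits was not computed.

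In vascular smooth muscle cells, 5 genes rose and 0 fell among 7108 tested (edgeR adjusted p under 0.05). FKBP5, a co-chaperone of the glucocorticoid receptor that the hormone itself induces, rose from 210 ± 196 to 3458 ± 392 CPM (log2 change 4.02 ± 0.55, adjusted p = 0.0217). NPPA rose from 7.62 to 359 ± 314 CPM (5.39 ± 0.72, adjusted p = 0.0217), the synaptic adhesion gene NRXN3 from 7.97 to 86.6 CPM (3.32 ± 0.42, adjusted p = 0.0204) and PLD5 from 56.1 to 379 CPM (2.70 ± 0.32, adjusted p = 0.0204). The remaining gene, TMEM38B, an ion channel gene of intracellular stores, was named after its values were seen (2.19 ± 0.32, adjusted p = 0.0332). FKBP5 (ENSG00000096060) lies on chromosome 6 at 35573585 to 35728583. At an unadjusted p under 0.05 there were 619 genes.

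Glucocorticoid-induced genes were higher as a list in smooth muscle cells (15 measured, median 0.98, camera adjusted p = 4.83e-05, adjusted p = 0.0948 with an estimated correlation). FKBP5 rose over all genes, and 7 rose and 2 fell adjusted over the list alone. The zinc finger gene ZBTB16 went from 671 to 2820 CPM and the metallothionein gene MT2A from 153 to 566 CPM. Mural contractile genes were lower (15 measured, median −0.42, adjusted p = 0.0369, adjusted p = 0.693 with an estimated correlation). Adjusted over the list alone 2 fell, the smooth muscle coactivator gene MYOCD (696 to 306 CPM) and the desmin gene DES (800 to 468 CPM). Glycolysis genes (16 measured, median −0.19, adjusted p = 0.0376, adjusted p = 0.441 with an estimated correlation), heat shock proteins (12 measured, median −0.52, adjusted p = 0.0369, adjusted p = 0.693 with an estimated correlation) and hypoxia genes (11 measured, median −0.42, adjusted p = 0.0376, adjusted p = 0.392 with an estimated correlation) were lower with 0 members past either adjustment. All of these lower calls were lost in some fit with 1 library left out. The camera adjusted p reached 0.52 for mural contractile genes, 0.576 for heat shock proteins, 0.248 for glycolysis and 0.0711 for hypoxia genes. For glucocorticoid-induced genes it was at most 0.000313. Of 22 extracellular matrix genes, 4 rose, among them ELN and FN1, and THBS1 fell adjusted over the list alone (median 0.02, adjusted p = 0.19). Fatty acid oxidation (median 0.08, adjusted p = 0.829, PDK4 rising adjusted over the list alone), oxidative phosphorylation (−0.12, adjusted p = 1) and immediate early genes (−0.86, adjusted p = 0.188) did not pass. Nor did interferon response (0.04, adjusted p = 0.829), NF-kB and cytokine genes (−0.43, adjusted p = 0.321) and TGF-beta response (−0.04, adjusted p = 0.544, 1 rising and 1 falling adjusted over the list alone). Fibroblast markers were higher (median 0.46, adjusted p = 0.0211, adjusted p = 0.185 with an estimated correlation). Markers of pericytes (median −0.65) and myeloid cells (median −1.08) were lower (adjusted p = 0.0092 for both, adjusted p = 0.185 with an estimated correlation for both). The sums rested on between 76 and 227 nuclei per library, all of cluster 18. The count of 5 became 8 without healthy replicate 1, 3 without healthy replicate 2, 26 without healthy replicate 3, 0 without NICM replicate 2 and 1 without NICM replicate 3. DESeq2 called 75 genes.

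Among the gene lists tested in cardiomyocytes, the largest median changes were in heat shock and immediate early genes. Heat shock genes, which code for chaperones, and immediate early genes were lower in NICM as lists. Their median log2 changes were −4.35 (16 measured, camera adjusted p = 0.000169, adjusted p = 0.755 with an estimated correlation) and −3.79 (19 measured, adjusted p = 4.72e-07, adjusted p = 0.686 with an estimated correlation). Adjusted over the list alone, 13 heat shock and 15 immediate early genes fell and 0 rose. HSPA1B was at 385 and 5.17 CPM, BAG3 at 937 and 24.7 CPM and FOS at 886 and 3.38 CPM in healthy and NICM libraries. Most of this came from 1 library: without healthy replicate 1 the medians were −0.32 and −1.12. The natriuretic peptide genes NPPA (14.7 and 171 CPM, log2 change 3.54 ± 0.95) and NPPB (14.8 and 165 CPM, 3.48 ± 1.07) and the foetal troponin gene TNNI1 (0.459 and 5.86 CPM) rose adjusted over the list alone.

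By edgeR 0 of 16414 genes changed in cardiomyocytes, with 1615 at an unadjusted p under 0.05 and 319 called by DESeq2. The groups did not overlap in 15.005% of genes, where chance gives 10%. Without healthy replicate 1 the count was 1. In the stress and foetal list, 4 of 17 rose and 1, the sarcomere repair gene XIRP1 (881 and 49.9 CPM), fell adjusted over the list alone (median −0.99, camera adjusted p = 0.747). The log2 change of XIRP1 was −4.14, and −2.20 without healthy replicate 1. Glycolysis genes were lower (19 measured, median −0.53, adjusted p = 0.00192, adjusted p = 0.686 with an estimated correlation), LDHA (−2.25) and PFKFB2 (−1.40) falling adjusted over the list alone. The lists of NF-kB and cytokine genes (16 measured, median −1.11, adjusted p = 0.00287, adjusted p = 0.686 with an estimated correlation) and of beta-adrenergic and cAMP genes (17 measured, median −0.99, adjusted p = 0.00192, adjusted p = 0.686 with an estimated correlation) were lower with 0 members past either adjustment. With 1 library left out, the camera adjusted p reached 0.12 for NF-kB and cytokine genes and 0.184 for beta-adrenergic and cAMP genes. For glycolysis, heat shock and immediate early genes it stayed under 0.05. These lists did not pass: sarcomere (median −0.38, adjusted p = 0.607), calcium handling (−0.38, adjusted p = 0.105), and cardiac ion channels (−0.06, adjusted p = 0.514). The same held for fatty acid oxidation (−0.24, adjusted p = 0.747), oxidative phosphorylation (0.04, adjusted p = 0.607) and branched-chain amino acid breakdown (0.05, adjusted p = 0.747). The calcium release channel gene RYR2 had a log2 change of −0.65 ± 0.61 and the calcium pump gene ATP2A2 of −0.86 ± 0.45. Glucocorticoid-induced genes (0.12, adjusted p = 0.207) held 1 that rose adjusted over the list alone, FKBP5 (174 and 979 CPM), and hypoxia genes (−0.83, adjusted p = 0.0573) held 1 that fell, NDRG1. Interferon response (−0.40, adjusted p = 0.453), extracellular matrix (0.05, adjusted p = 0.747) and TGF-beta response (−0.27, adjusted p = 0.667) did not pass. Markers of endothelial cells (median −0.98, adjusted p = 0.000707, adjusted p = 0.75 with an estimated correlation) and myeloid cells (−1.14, adjusted p = 1.92e-06, adjusted p = 0.182 with an estimated correlation) were lower. Those of lymphocytes were higher (0.66, adjusted p = 0.0293, adjusted p = 0.75 with an estimated correlation). Different clusters held the cardiomyocytes of the libraries. Clusters 2, 43 and 44 held 83.05%, 97.2% and 93.8% of those of healthy replicates 1, 2 and 3, cluster 2 with the stress genes BAG3 and NR4A3 among its leading genes. Cluster 34 held 88.8% of NICM and 0.780% of healthy cardiomyocytes.

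Endothelial cells of NICM hearts had higher glucocorticoid-induced and interferon genes and lower NF-kB and cytokine genes as lists with the preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.369, 0.438 and 0.369) or with fry. FKBP5 was at 131 and 1349 CPM (log2 change 3.37 ± 0.43), MT2A at 55.5 and 374 CPM and ZBTB16 was 2.54 ± 0.61 higher on the log2 scale. In all 8 of 19 glucocorticoid-induced genes rose and 0 fell adjusted over the list alone (median 1.51, camera adjusted p = 1.96e-07, adjusted p = 0.369 with an estimated correlation). Of 26 interferon response genes, 25 had positive changes (median 0.44, adjusted p = 1.3e-06, adjusted p = 0.438 with an estimated correlation), with 0 past either adjustment. The adhesion molecule genes of activated endothelium SELE (205 and 3.45 CPM), ICAM1 (105 and 23.9 CPM) and VCAM1 (132 and 36.3 CPM) fell adjusted over the list alone in the venous and activated list (13 measured, median −0.59, adjusted p = 0.0115, adjusted p = 0.369 with an estimated correlation).

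No gene passed in endothelial cells over all genes: edgeR called 0 of 15456, with 1503 at an unadjusted p under 0.05 and 345 called by DESeq2. The groups did not overlap in 14.0% of genes (10% by chance). Without NICM replicate 2 the count was 1. NF-kB and cytokine genes were lower (20 measured, median −0.36, adjusted p = 3.44e-05, adjusted p = 0.369 with an estimated correlation). Of these, 7 fell adjusted over the list alone, IL6 and CCL2 included. Extracellular matrix genes were higher (28 measured, median 0.45, adjusted p = 0.00236, adjusted p = 0.438 with an estimated correlation). Adjusted over the list alone 5 rose, POSTN and ELN among them, and LAMC1 fell. Heat shock proteins (16 measured, median −0.40, adjusted p = 0.00236, adjusted p = 0.52 with an estimated correlation) and immediate early genes (21 measured, median −1.31, adjusted p = 0.000473, adjusted p = 0.52 with an estimated correlation) were lower with 0 past either adjustment. Without healthy replicate 1 their medians were −0.17 and −0.70. With 1 library left out, the camera adjusted p reached 0.0933 for heat shock proteins and 0.119 for immediate early genes. It reached 0.22 for extracellular matrix and 0.0636 for the venous and activated list. It stayed under 0.05 for the glucocorticoid-induced, interferon, and NF-kB and cytokine lists. The arterial list had 3 rises adjusted over the list alone, BMX, HEY1 and JAG1 (14 measured, median 0.31, adjusted p = 0.0804). The capillary list had 2, RGCC and LPL, and 1 fall, TCF15 (16 measured, median 0.20, adjusted p = 0.224). Fatty acid oxidation (0.05, adjusted p = 0.189), oxidative phosphorylation (0.01, adjusted p = 0.26, ATP5PO rising adjusted over the list alone) and glycolysis (−0.31, adjusted p = 0.0638) did not pass. Nor did hypoxia genes (−0.23, adjusted p = 0.26, ANKRD37 falling adjusted over the list alone) and TGF-beta response (−0.18, adjusted p = 0.61, 3 rising and 2 falling adjusted over the list alone). Markers of smooth muscle cells (median 0.64, adjusted p = 0.0178) and lymphocytes (0.94, adjusted p = 0.0106) were higher and those of myeloid cells lower (−0.54, adjusted p = 0.00632), each with adjusted p = 0.259 with an estimated correlation. Cluster 9 came to 99.1% from 1 healthy library, cluster 16 held 44.0% of NICM and 0.682% of healthy endothelial cells, and cluster 26, led by the arterial genes SEMA3G and GJA5, held 15.8% and 5.30%.

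Pericytes of NICM hearts had higher glucocorticoid-induced genes and lower immediate early and cytokine genes as lists with the preset correlation. None of these calls held with an estimated correlation (adjusted p = 0.533, 0.533 and 0.426) or with fry. FKBP5 was at 110 and 795 CPM (log2 change 2.85 ± 0.41). ZBTB16 and PIK3R1 also rose and CRISPLD2 fell adjusted over the list alone (18 measured, median 0.41, camera adjusted p = 0.0108, adjusted p = 0.533 with an estimated correlation). LAMB1, at 135 and 510 CPM, rose adjusted over the list alone in the extracellular matrix list (25 measured, median 0.22, adjusted p = 0.0155, adjusted p = 0.426 with an estimated correlation). Immediate early genes were lower (18 measured, median −1.79, adjusted p = 4.82e-05, adjusted p = 0.533 with an estimated correlation), with a median of −0.34 without healthy replicate 1.

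By edgeR 0 of 12314 genes changed in pericytes, with 921 at an unadjusted p under 0.05 and 146 called by DESeq2. The groups did not overlap in 12.977% of genes (10% by chance). The count was 8 without healthy replicate 3 and 1 without healthy replicate 2 or without NICM replicate 3. NF-kB and cytokine genes (11 measured, median −0.68, adjusted p = 0.00667, adjusted p = 0.426 with an estimated correlation) were lower, CCL2 and NFKBIZ falling adjusted over the list alone. Heat shock proteins (16 measured, median −0.45, adjusted p = 0.0108, adjusted p = 0.533 with an estimated correlation) and hypoxia genes (14 measured, median −0.31, adjusted p = 0.0155, adjusted p = 0.426 with an estimated correlation) were lower with 0 past either adjustment. Without healthy replicate 1 the heat shock median was −0.09. With 1 library left out, the camera adjusted p reached 0.223 for glucocorticoid-induced genes, 0.0947 for immediate early genes and 0.155 for extracellular matrix. It reached 0.316 for heat shock proteins and 0.061 for hypoxia genes, and at most 0.0125 for NF-kB and cytokine genes. Of 15 mural contractile genes, MYH11 rose and SYNPO2 fell adjusted over the list alone (median −0.26, adjusted p = 0.74). Fatty acid oxidation (−0.01, adjusted p = 0.74), oxidative phosphorylation (−0.04, adjusted p = 0.967), glycolysis (−0.10, adjusted p = 0.0704), interferon response (0.16, adjusted p = 0.156) and TGF-beta response (0.03, adjusted p = 0.665, 1 rising and TGFBI falling adjusted over the list alone) did not pass. Fibroblast markers were higher (median 0.68, adjusted p = 9.41e-05, adjusted p = 0.204 with an estimated correlation) and myeloid markers lower (−0.85, adjusted p = 6.67e-06, adjusted p = 0.145 with an estimated correlation). Cluster 15 held 66.1% of healthy and 97.2% of NICM pericytes, and cluster 17 came to 98.4% from 1 healthy library.

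Myeloid cells, mainly macrophages, had higher glucocorticoid-induced genes as a list in NICM (adjusted p = 0.111 with an estimated correlation), while genes of monocytes and monocyte-derived macrophages went both ways. ZBTB16 was at 96.0 and 2108 CPM (log2 change 4.45 ± 0.76), and FKBP5 was 2.84 ± 0.63 higher on the log2 scale. KLF9, TSC22D3 and MT2A were among the 8 of 18 glucocorticoid-induced genes that rose, with 1 falling, adjusted over the list alone (median 0.91, camera adjusted p = 1.66e-05, adjusted p = 0.111 with an estimated correlation). CCR2, the receptor by which monocytes enter tissue (15.2 and 3.63 CPM), the calprotectin genes S100A8 (73.2 and 15.4 CPM) and S100A9 (106 and 19.1 CPM) and VCAN were among 7 of 19 genes of monocytes and monocyte-derived macrophages that fell adjusted over the list alone. CLEC4E, CXCR4 and LPL rose (median −1.22, adjusted p = 0.0846). The mannose receptor gene MRC1, a gene of resident macrophages, rose (1.64 ± 0.32) and CD209 fell (−0.90 ± 0.19) adjusted over the list alone (18 measured, median 0.11, adjusted p = 0.412).

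By edgeR 0 of 15146 genes changed in myeloid cells, with 2282 at an unadjusted p under 0.05 and 799 called by DESeq2. The groups did not overlap in 19.8% of genes (10% by chance). Without healthy replicate 3 the count was 327. Oxidative phosphorylation genes were higher (32 measured, 29 positive, median 0.39, adjusted p = 7.69e-05, adjusted p = 0.776 with an estimated correlation), ATP5PO and SDHD rising adjusted over the list alone. Immediate early genes (22 measured, median −1.23, with 0 past either adjustment) and NF-kB and cytokine genes (21 measured, median −0.79, with CCL2 falling adjusted over the list alone) were lower (adjusted p = 0.0307 for both, adjusted p = 0.776 with an estimated correlation for both). Without healthy replicate 1 the immediate early list had a test direction of up (adjusted p = 0.835). Fatty acid oxidation (0.10, adjusted p = 0.0846, LPL and PDK4 rising adjusted over the list alone), glycolysis (−0.13, adjusted p = 0.819) and heat shock proteins (−0.25, adjusted p = 0.182) did not pass. Nor did hypoxia genes (−0.24, adjusted p = 0.373), interferon response (0.08, adjusted p = 0.13), extracellular matrix (0.10, adjusted p = 0.13, 1 rising adjusted over the list alone) and TGF-beta response (−0.16, adjusted p = 0.366, 1 rising and 2 falling adjusted over the list alone). Lymphocyte markers were higher (median 0.52, adjusted p = 0.0315, adjusted p = 0.373 with an estimated correlation). Cluster 8, with MRC1 and CD163 among its leading genes, held 3.95% of healthy and 80.7% of NICM myeloid cells. Clusters 6 and 7 held 49.4% and 24.7% of the healthy and 0.615% and 0.123% of the NICM ones, so values within this type compare different clusters.

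Lymphocytes had higher glucocorticoid-induced genes as a list in NICM. ZBTB16 (log2 change 1.92 ± 0.32), FKBP5 (1.93 ± 0.42) and TSC22D3 (173 and 488 CPM) were among 7 of 15 glucocorticoid-induced genes that rose, with 1 falling, adjusted over the list alone (median 0.84, camera adjusted p = 1.75e-05, adjusted p = 0.281 with an estimated correlation). In the T cell activation and exhaustion list the early activation gene CD69 (271 and 669 CPM), the chemokine gene CCL4 (108 and 204 CPM) and the inhibitory receptor gene CTLA4 (8.13 and 27.1 CPM) rose and TNF fell adjusted over the list alone (17 measured, median 0.22, adjusted p = 0.0984). By edgeR 0 of 10899 genes changed, with 875 at an unadjusted p under 0.05 and 134 called by DESeq2. The groups did not overlap in 13.4% of genes (10% by chance). Without healthy replicate 3 the count was 5 and without NICM replicate 3 it was 2. Oxidative phosphorylation genes (32 measured, median 0.18, adjusted p = 0.0125, adjusted p = 0.589 with an estimated correlation) and extracellular matrix genes (22 measured, median 0.32, 4 rising adjusted over the list alone, adjusted p = 0.0125, adjusted p = 0.589 with an estimated correlation) were higher. Heat shock proteins (15 measured, median −0.40, adjusted p = 0.0402, adjusted p = 0.8 with an estimated correlation) and immediate early genes (14 measured, median −1.07, adjusted p = 0.00816, adjusted p = 0.702 with an estimated correlation) were lower with 0 past either adjustment. Without healthy replicate 1 both lists had an adjusted p = 0.851, heat shock proteins with a test direction of up. Of 14 NF-kB and cytokine genes, NFKBIA, TNFAIP3 and 1 other rose and ICAM1 and 1 other fell adjusted over the list alone (median −0.55, adjusted p = 0.152). Fatty acid oxidation (−0.01, adjusted p = 0.753), glycolysis (0.01, adjusted p = 0.753), hypoxia genes (−0.11, adjusted p = 0.913), interferon response (−0.06, adjusted p = 0.928) and TGF-beta response (−0.15, adjusted p = 0.753, CTGF rising and 2 falling adjusted over the list alone) did not pass. Markers of cardiomyocytes (median 0.32, adjusted p = 0.015, adjusted p = 0.568 with an estimated correlation), fibroblasts (0.25, adjusted p = 0.015, adjusted p = 0.19 with an estimated correlation) and smooth muscle cells (0.60, adjusted p = 0.015, adjusted p = 0.19 with an estimated correlation) were higher. Those of endothelial cells were lower (−0.64, adjusted p = 0.00101, adjusted p = 0.568 with an estimated correlation).

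**Figure D3:**
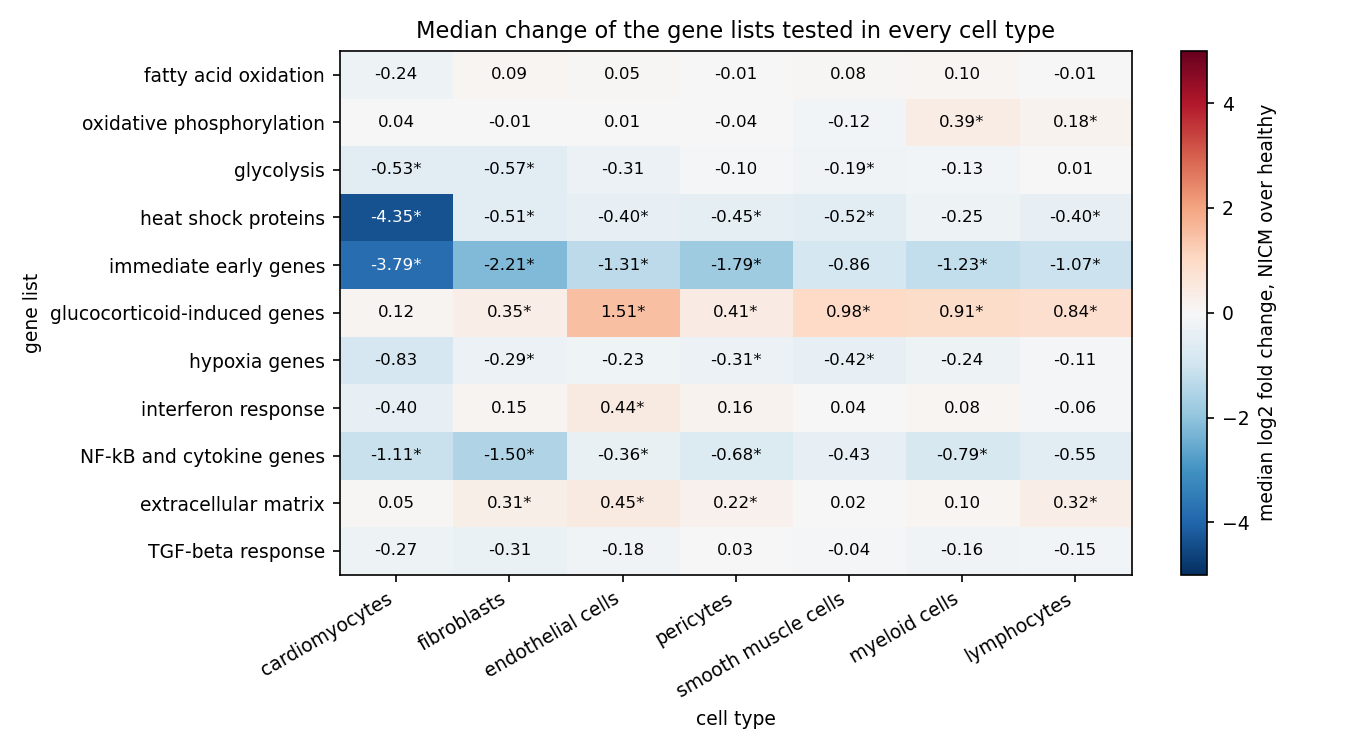
Median log2 fold change, NICM over healthy (colour and printed value), of the 11 gene lists tested in every type (vertical axis) in the 7 tested cell types (horizontal axis), with a star where camera with the preset correlation gave an adjusted p under 0.05. Immediate early genes have a negative median in all 7 types and glucocorticoid-induced genes a positive one, from 0.12 in cardiomyocytes to 1.51 in endothelial cells, and 0 of the starred calls held with an estimated correlation.

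Across the 7 types camera called 58 of 153 list tests, 24 higher and 34 lower, counting gene lists and marker lists together, and 0 of the 58 held with an estimated correlation. In 18 of the 153, all of them uncalled, the median, the mean and the direction of the test were not of 1 sign. In all 7 types FKBP5 and NPPA were higher in every NICM library than in every healthy one. FKBP5 passed over all genes in smooth muscle cells, and NPPA in fibroblasts and smooth muscle cells. The level of NPPA in NICM libraries was much alike across types before TMM scaling, at 192 CPM in cardiomyocytes, 227 in fibroblasts, 337 in smooth muscle cells, 385 in endothelial cells and 472 in lymphocytes.

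**Figure D4:**
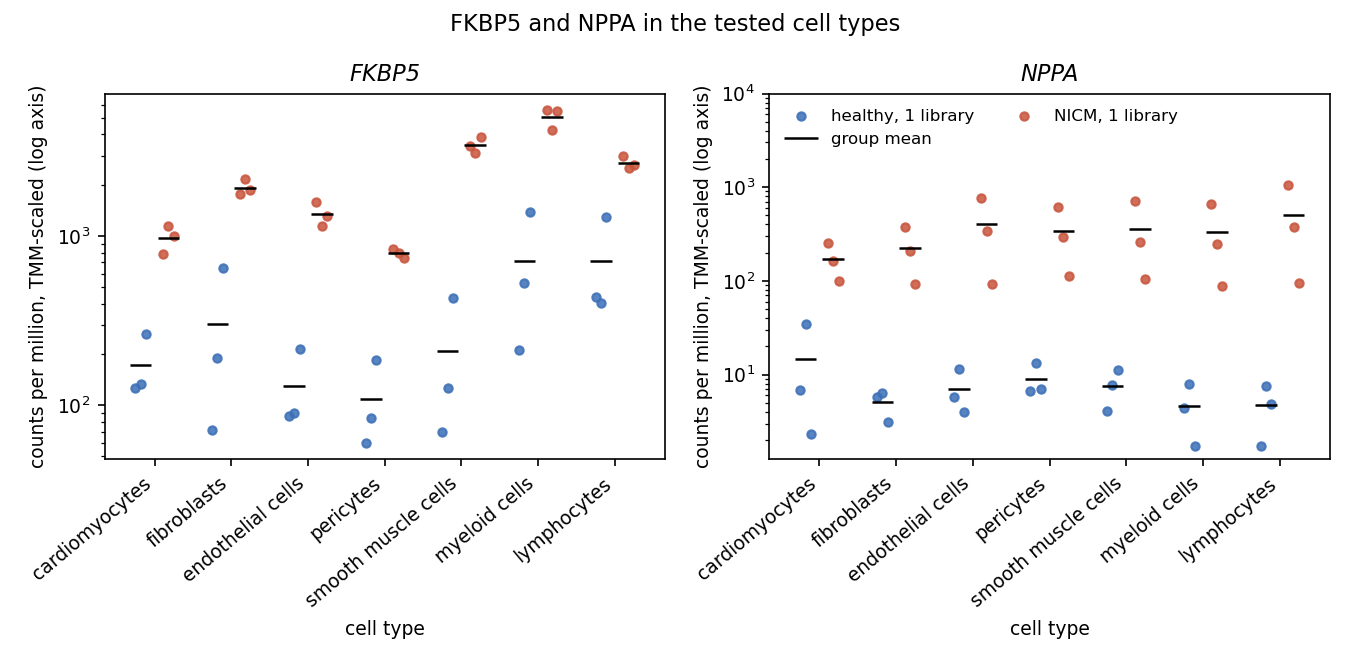
TMM-scaled CPM (vertical log axes) of FKBP5 (left) and NPPA (right) in the 7 tested cell types (horizontal axes), with 1 point per healthy (blue) or NICM (red) library and the group mean as a bar. FKBP5 means in NICM range from 795 CPM in pericytes upward, and the NICM points lie above the healthy points for both genes in every type.

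Whether a gene's change differed between fibroblasts and another type was tested directly. Against cardiomyocytes 1 of 14880 genes differed, WNT9A, a WNT ligand gene, and against myeloid cells 1 of 14144, SEZ6L (limma adjusted p = 0.00356 and 0.0147). SEZ6L had a log2 change of 3.48 in fibroblasts and −0.36 in myeloid cells, and WNT9A of −0.94 in fibroblasts and 4.41 in cardiomyocytes. Against endothelial cells 0 of 14621 genes differed by limma, with 1369 at an unadjusted p under 0.05, and against pericytes 0 of 12157, with 974. No other tool was run on these differences.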

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

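The tests of tissue handling, of free RNA by UMIs per nucleus, of free RNA for NPPB, of differences between cell types and of the unnamed clusters, and the limit on shared barcodes, were chosen after results or barcodes were seen.

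The change of WNT9A differed between cell types. Its log2 change, NICM over healthy, was −0.94 in fibroblasts and 4.41 in cardiomyocytes, a difference of −5.34 ± 0.27 SE (limma on differences within libraries, adjusted p = 0.00356 over 14880 genes). The TMM-scaled means were 20.7 and 9.87 CPM in fibroblasts and 3.06 and 61.2 CPM in cardiomyocytes, and neither change passed within its type. The change of SEZ6L differed between fibroblasts (3.48) and myeloid cells (−0.36), by 3.84 ± 0.26 SE (adjusted p = 0.0147 over 14144 genes). No biological or technical explanation of these differences was tested.

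Barcodes were shared between a pair of matrices from different groups. Of the barcodes of 1 healthy matrix, 92.5% also stood in 1 NICM matrix, 9750 barcodes where chance gives 294, while the other pairs shared between 127 and 368. The shared barcodes held a median of 1225 UMIs in the NICM matrix and 3931 in the healthy one. With the smaller of the pair's counts taken for each gene, the overlap was 91.2% of a shared barcode's UMIs in the NICM matrix at the median. This is an overlap of counts, not of identified molecules. It is raised by the greater depth of the healthy matrix and was not computed for shuffled barcodes. The expression of the same barcode in the pair correlated at 0.868, against 0.476 for shuffled barcodes. These values are across genes within a barcode, not across samples. The shared barcodes held 31.6% of the UMIs of that NICM matrix and were removed from it. No explanation was tested.

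Cluster 21, which took no cell type's name, made up 4.87% ± 2.38 of NICM and 0.503% ± 0.0826 of healthy libraries, and the lowest NICM library had 5.51 times the share of the highest healthy one (exact permutation p = 0.1, the smallest the design allows). It held markers of both smooth muscle cells and fibroblasts, with CNTNAP2, PLD5, NPY1R and ITGA8 among its leading genes. The mix was uneven: the mean z score was 2.19 for smooth muscle cells, with 9 of 10 markers seen, and 1.12 for fibroblasts. The fibroblast score lay just over the bound of 1 that left the cluster unnamed. Its 1396 kept nuclei, against 755 in the named smooth muscle cells, are not in the share of that type. PLD5 also rose in smooth muscle cells. Whether nuclei were placed in this cluster by differences in expression between the groups was not tested.

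Immediate early genes had a negative median change in NICM in 7 of 7 tested types, which tissue handling before the nuclei were isolated and disease of the whole heart both predict, though in endocardial cells, not among the tested types, FOS was higher in every NICM library (163 and 847 CPM without TMM scaling, exact permutation p = 0.1), in nuclei that lay mostly in cluster 12 in healthy and in cluster 42 in NICM libraries. At the median of the list, the type with the most UMIs per nucleus stood at least 8.38 times above the lowest type in each healthy library. In CPM the same ratio was at least 4.77. These ratios argue against free RNA as the only source in every type, in a like amount per droplet or a like share of all UMIs. They do not test whether free RNA gave the levels in the lowest types, and low counts in a type can enlarge them. Whether 1 healthy library carries the pattern stays open: without healthy replicate 1 the median was −0.34 in pericytes, above the bound of −0.5 set for that explanation, but −1.12 in cardiomyocytes, −0.73 in fibroblasts and −0.70 in endothelial cells. That bound was set for these types alone. Without the same library the list also no longer passed in myeloid cells (camera adjusted p = 0.835, test direction of up) and lymphocytes (camera adjusted p = 0.851). In smooth muscle cells it had not passed with all libraries. Handling and disease cannot be told apart, because no label gives the time from heart to freezing and any such time may follow the groups, and a biological difference stays open and untested.

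NPPA and NPPB were higher in NICM fibroblasts and NPPA in smooth muscle cells. Free RNA of any source predicts like levels in every type, and in each of the 3 NICM libraries NPPA in these types was at most 1.09 times, and NPPB in fibroblasts at most 0.925 times, the median level in endothelial cells, pericytes, myeloid cells and lymphocytes. The rises of NPPA and NPPB may therefore be free RNA rather than expression by these cells. Cardiomyocytes as the source were tested through their other markers: the ratio of fibroblast to cardiomyocyte level was at least 7.29 times that of the markers. This leaves the source open, because the markers were measured in nuclei while free RNA may come from the cytoplasm, where the ratio of these transcripts was not measured.

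Glucocorticoid-induced genes were higher as a list in 6 of the 7 tested types with the preset correlation and in 0 with an estimated one (adjusted p between 0.0948 and 0.755), and did not pass in cardiomyocytes (camera adjusted p = 0.207, mean log2 change −0.19). For endothelial cells, smooth muscle cells, myeloid cells and lymphocytes, that 1 NICM library carries this is argued against. With each NICM library left out in turn, the lowest median log2 change over these types was 0.65. Fibroblasts and pericytes were not in this test. With 1 library of either group left out, the camera adjusted p of the list reached 0.034 in fibroblasts and 0.223 in pericytes. At the median of the list, the highest type stood at least 11.7 times above the lowest type in CPM within each NICM library. In UMIs per nucleus it stood at least 10.1 times above. These ratios argue against free RNA as the only source of these genes in every type. They do not test whether the rise in the lowest types came from free RNA, and low counts in a type can enlarge them. A candidate explanation is exposure to glucocorticoids, natural or given as treatment, and it was not tested, since no label analysed here gives treatment. Disease itself stays open as well, and so does library chemistry, which is not given per library. In 14 of 15 pairs the matrices shared barcodes at 0.893 to 1.07 times 1 common rate. That rate, which implies a list of 719195 barcodes, was fitted to the same pairs, so it does not settle the chemistry.

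With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For genes past the threshold, the real count and the highest of the other splits were 49 and 0 in fibroblasts (1 split with a count as large, the real one included), 5 and 1 in smooth muscle cells (1 split), 0 and 1 in pericytes (10 splits), and 0 and 0 in cardiomyocytes, endothelial cells, myeloid cells and lymphocytes (10 splits each). For gene lists with the preset correlation, they were 8 and 7 in fibroblasts (1 split), 5 and 4 in smooth muscle cells (1 split), 7 and 7 in endothelial cells (2 splits), 5 and 7 in lymphocytes (3 splits), 6 and 9 in pericytes (4 splits), 5 and 10 in cardiomyocytes (9 splits) and 4 and 8 in myeloid cells (9 splits). For differences from fibroblasts, they were 1 and 1 for cardiomyocytes (2 splits), 1 and 0 for myeloid cells (1 split), 0 and 0 for endothelial cells (10 splits) and 0 and 1 for pericytes (10 splits).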

How the results depend on the processing

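The alternative with shared barcodes kept was chosen after the barcodes were seen, and the others before the data were examined. No paired analysis was possible because the replicate numbers follow the order of the samples and pair nothing. A fit with library chemistry as a term was not run, since the chemistry is not given per library. Where a value moved, the cause was not tested. Of 14 shares, all kept their direction with doublets kept, with the automatic doublet threshold, at 1000 UMIs per nucleus and in edgeR. Groups also did not overlap in pericytes at 1000 UMIs per nucleus, and in pericytes and fibroblasts at Leiden resolution 2.0 (exact permutation p = 0.1 each). The endothelial share reversed to a difference of 1.19 percentage points with shared barcodes kept, and that of smooth muscle cells to 0.0936 at Leiden resolution 2.0. With 1 library left out, differences in share ranged from −4.69 to 3.62 for endothelial cells, −3.66 to 0.947 for endocardial cells, −0.293 to 0.255 for smooth muscle cells, −0.145 to 0.00396 for B cells and −0.0624 to 1.56 for adipocytes. Without a change of direction they ranged from −8.59 to −0.0987 for cardiomyocytes, −10.6 to −4.23 for pericytes, 3.68 to 9.24 for fibroblasts, 1.16 to 5.32 for myeloid cells, 0.313 to 1.60 for lymphocytes, 1.04 to 1.71 for lymphatic endothelial cells, −1.14 to −0.444 for mast cells, −0.674 to −0.0698 for neuronal cells and −0.35 to −0.0309 for mesothelial cells. With 1 library left out, differences in depth ranged from −737 to 387 UMIs and −297 to 105 genes per nucleus. Counts of changed genes in cardiomyocytes, fibroblasts, endothelial cells, pericytes, smooth muscle cells, myeloid cells and lymphocytes were 7, 452, 143, 419, 230, 392 and 372 without a filter on low counts and 319, 675, 345, 146, 75, 799 and 134 by DESeq2. With 1 library left out they ranged from 0 to 1, 0 to 41, 0 to 1, 0 to 8, 0 to 26, 0 to 327 and 0 to 5 in the same order. Single libraries decided some counts: 327 genes in myeloid cells without healthy replicate 3, 26 in smooth muscle cells without healthy replicate 3, and 0 in fibroblasts and in smooth muscle cells without NICM replicate 2. Fibroblasts had 20 genes at Leiden resolution 2.0 and 6 with shared barcodes kept, all 20 and all 6 among the 49. Without healthy replicate 3 and without NICM replicate 1 they had 41 and 33, of which 20 and 17 were among the 49. Smooth muscle cells had 3 genes at Leiden resolution 2.0 and 9 with genes that free RNA can give left out. That setting tested 6727 of the 7108 genes and still held all 5 of the main calls, NPPA included, so it says nothing on whether these come from free RNA. Lymphocytes had 2 with DESeq2 size factors, 4 with genes that free RNA can give left out, 2 at 1000 UMIs per nucleus and 3 at Leiden resolution 2.0. Gene lists fell to 0 in each of the 7 types with an estimated correlation, and with fry to 0 except 1 in fibroblasts (hypoxia genes) and 1 in myeloid cells (glucocorticoid-induced genes). Marker lists fell to 0 in each of the 7 types with both. Of the 58 called lists, 58 held with DESeq2 size factors, 55 with doublets kept and 47 with shared barcodes kept. Without healthy replicates 1 to 3 and NICM replicates 1 to 3, 43, 44, 44, 50, 39 and 46 held. Gene lists numbered 3 in lymphocytes with doublets kept and 1 in smooth muscle cells with shared barcodes kept, and marker lists 3 in myeloid cells with shared barcodes kept. With 1 library left out, gene lists ranged from 5 to 8 in cardiomyocytes, 3 to 9 in pericytes, 1 to 6 in smooth muscle cells, 2 to 7 in myeloid cells and 3 to 7 in lymphocytes, and marker lists from 1 to 3 in fibroblasts, 2 to 6 in endothelial cells, 2 to 5 in pericytes, 0 to 4 in smooth muscle cells, 0 to 3 in myeloid cells and 0 to 4 in lymphocytes. Without healthy replicate 1, immediate early genes as a list in myeloid cells (adjusted p from 0.00084 to 0.835 over the libraries left out) and heat shock proteins as a list in lymphocytes (0.000588 to 0.851) turned to a test direction of up. Of 154 named values, 154 kept direction and side of the threshold with DESeq2 size factors, with doublets kept and at 1000 UMIs per nucleus. None changed direction in any setting; 14 lost and 1 gained the threshold at Leiden resolution 2.0, 19 lost it with shared barcodes kept, and 80 gained it without a filter and 98 of 149 by DESeq2. Without healthy replicates 1 to 3 and NICM replicates 1 to 3, 24, 17, 10, 15, 30 and 27 lost it and 0, 0, 19, 3, 0 and 2 gained it. Recovery of simulated 4-fold changes did not follow depth: it was 82% in smooth muscle cells, with 255595 UMIs in the lowest library. In cardiomyocytes, with the most UMIs and the largest spread between people, it was 2%. The changed genes were drawn from those past the count filter in each type, 7108 in smooth muscle cells and 16414 in cardiomyocytes. These rates therefore rest on different genes and do not separate depth from spread.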

Other observations

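The comparisons in this part were chosen after the changes in the tested types were seen. In 4 types that were not tested across genes, FKBP5 was also higher in every NICM library than in every healthy one, in CPM without TMM scaling. Its means were 191 and 4266 CPM in endocardial cells, 181 and 828 CPM in lymphatic endothelial cells, 478 and 2627 CPM in mast cells and 390 and 1302 CPM in neuronal cells (exact permutation p = 0.1 each, the smallest the design allows). ZBTB16 did the same in endocardial cells (370 and 2370 CPM), lymphatic endothelial cells (276 and 1141 CPM), mast cells (148 and 1082 CPM) and neuronal cells (334 and 1636 CPM), with an exact permutation p = 0.1 each. Endocardial nuclei lay mostly in cluster 12 in healthy and in cluster 42 in NICM libraries, so their values compare different clusters. Values in B cells and adipocytes are not given, since some libraries held fewer than 20 of their nuclei.

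Among the other unnamed clusters, cluster 24, led by KCNJ15, MGAM and CSF3R, made up 1.45% of healthy and 1.04% of NICM libraries (exact permutation p = 0.5). Cluster 28, with markers of both myeloid cells and fibroblasts, made up 1.04% and 0.456% with no overlap (exact permutation p = 0.1). Before doublets were removed, 44.4% of its nuclei were called doublets and its UMIs stood at 2.23 times the median of their library, so the remaining nuclei may hold doublets too.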
